A study of Mus musculus with 12 samples.

How the data were processed

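Gene expression was measured in total RNA from the small intestine and colon of mice lacking Agr2 (KO) and of their wild-type (WT) littermates. Agr2 encodes a member of the protein disulfide isomerase family, enzymes of the endoplasmic reticulum that form disulfide bonds in proteins on their way to secretion. The labels give 12 samples, 1 array each, in 4 groups, with 4 KO and 4 WT arrays of small intestine and 2 KO and 2 WT arrays of colon. RNA was amplified, labelled with the single dye Cy3 and hybridized to Agilent mouse arrays of long oligonucleotide probes, per the labels' protocols. The labels number the samples within each group and do not say that every sample came from a separate animal, so p-values measure the spread between these samples, which may be partly technical.

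The arrays were read with Agilent Feature Extraction 9.1, per the submitters' processing notes. The deposited table holds log2 intensities of 41174 probes on the 12 arrays, with no missing values and no control spots. The log base was settled from the values: below 9, 2 raised to the power of each of the 6576 distinct values was a whole multiple of 1/48 for 100% of them, within 0.01 of a step, while for powers of e this held for 2.10%. Such steps fit a mean of intensities over the 12 arrays, and the 75th percentile was 10.34 on each of them. From these features, and from no statement in the labels, the deposited log2 values were taken to be quantile normalized between arrays. The background correction, the averaging of repeated spots and any filter applied before deposit are not given in the sources used here. Quantile normalization gives every array the same distribution, so a change in the total amount of RNA, or a shift shared by most probes, cannot show in these values. All differences below are relative to the other probes of the same array.

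The deposited table identifies probes by Agilent's probe IDs and does not pair them with genes. A RefSeq gene table (assembly GRCm38.p6) held 0 of these IDs, and no other probe annotation was used here. Results are therefore given per probe, and 1 gene can be measured by several probes. The level of Agr2 itself, which would check the genotype labels, and the 32 gene lists fixed before the data were examined were not analysed here. The tissue labels were checked by correlation between arrays and by principal component analysis.

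The values were analysed as deposited in R 4.3.3 with limma 3.58.1. A probe was kept if it lay above the array's 40th percentile on at least 2 of the 12 arrays, which kept 26980 probes and left out 14194 as dim. The mean of the 40th percentiles, a log2 intensity of 6.75, served as the dim limit. Linear models with 4 group means were fitted to all 12 arrays together (lmFit), so that the 4 groups shared an estimate of the spread per probe, and were moderated with an intensity trend (eBayes). The fit had 8 residual degrees of freedom and 2.78 prior degrees of freedom. The contrasts below were tested, two-sided: KO against WT in small intestine, KO against WT in colon, the difference between these effects (the interaction), and colon against small intestine in WT mice. P-values were adjusted over all probes of a contrast by the method of Benjamini and Hochberg, and a probe was called when its adjusted p was under 0.05. Differences are log2, KO minus WT, ± the limma standard error (SE), and levels are group means ± SD of log2 intensities. Where the dimmer group lay below the dim limit, the fold is the brighter group's mean against that limit and is given as "at least". The number of arrays limits the precision: the median SE over all probes was 0.151 in small intestine, with 4 arrays per genotype, and 0.214 in colon, with 2.

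Before the data were examined, the design called for 1 probe per gene, camera tests of the gene lists, and naming 11 fixed genes and the 8 largest rises and falls per KO comparison. Because the probes carry no gene names here, every kept probe was tested on its own, the lists were not tested, and the naming rule was reduced to the 2 probes with the largest rise and the 2 with the largest fall per KO comparison, among called probes whose KO and WT arrays of that tissue did not overlap. Correlations between the KO effects of different tissues are across probes, which are not independent replicates. Overlaps of calls were tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 4 tests. That test treats probes as independent, which probes of 1 gene and co-regulated genes are not.

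The procedure was tested on simulated data with 26980 probes and known changes. With arrays as unequal as the real ones, it called 62% of 2-fold and 96% of 4-fold changes in small intestine, and 24% of 2-fold and 85% of 4-fold changes in colon, with 3 false calls in each tissue. With equal arrays there were 9 false calls in small intestine and 5 in colon. The simulated spread was normal with 1 factor per array, so no simulated array held a set of strongly raised probes. Alternatives covered the scaling between arrays, the dim filter, the variance trend, array weights, a fit on the arrays of the compared tissue, a replicate block and leaving out each array of the groups compared in turn. A fit of all comparisons without 1 outlying array was added after the correlations between arrays had been seen. Plots were drawn with matplotlib 3.10.9.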

Results

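The arrays compared KO and WT mice in both parts of the gut, to ask which transcripts change in an intestine without Agr2, a disulfide isomerase made in mucus-secreting cells. Correlations of log2 intensities, across the 26980 probes kept, followed the tissue labels. Small intestine arrays other than KO replicate 4 correlated with each other at 0.974 to 0.992, colon arrays at 0.940 to 0.991, and small intestine with colon arrays at 0.891 to 0.920, again without KO replicate 4. The WT colon arrays correlated at 0.991, the KO colon arrays at 0.981, and KO with WT colon arrays at 0.940 to 0.971. The first principal component, with 57.4% of the variance, separated the tissues. KO small intestine replicate 4 stood apart on the second, with 14.1% of the variance. Its correlations with the other small intestine arrays were 0.936 to 0.947 and with the colon arrays 0.864 to 0.888, and 345 probes lay above their median by more than 3 log2 units, against 48 or fewer on any other small intestine array.

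**Figure D1:**
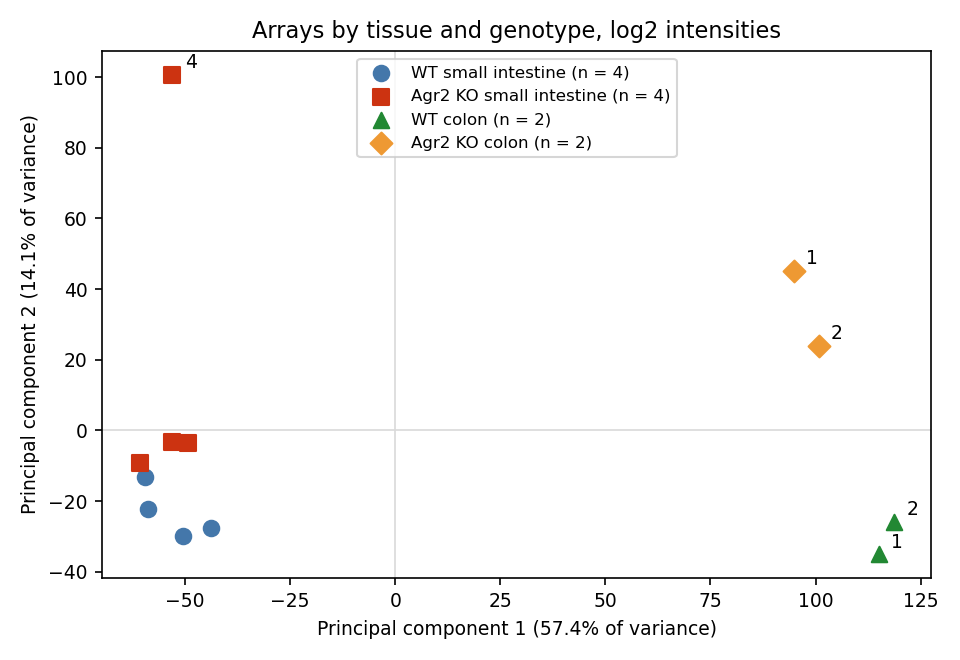
Each point is 1 of the 12 arrays, placed by the first principal component (horizontal, 57.4% of the variance) and the second (vertical, 14.1%) of the log2 intensities of 26980 probes, with colour and shape for the group and replicate numbers beside the colon arrays and KO small intestine replicate 4. The tissues lie on opposite sides of the first component, and KO small intestine replicate 4 lies away from the other 7 small intestine arrays on the second.

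**Figure D2:**
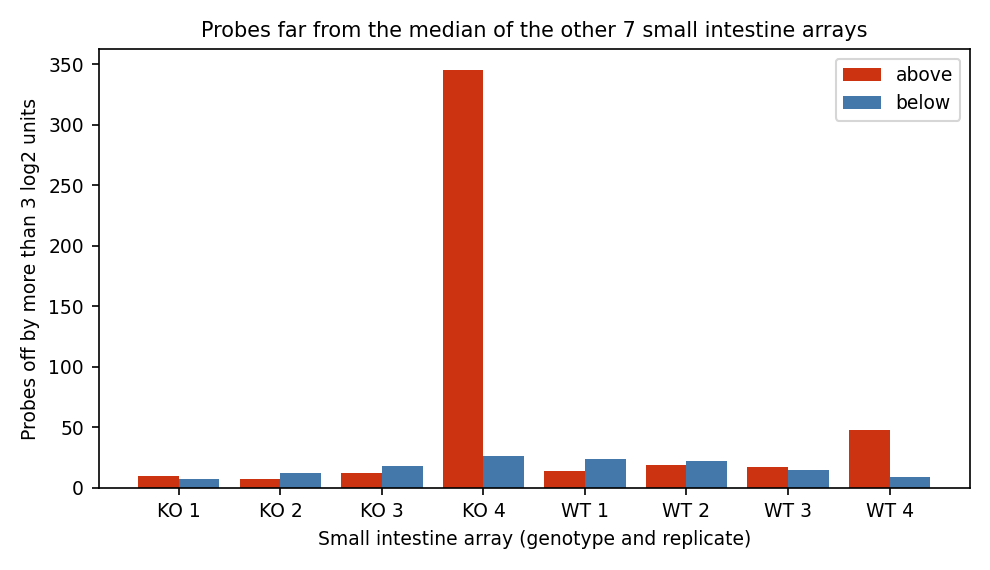
Bars give, for each of the 8 small intestine arrays, the number of probes above (red) or below (blue) the median of the other 7 by more than 3 log2 units. KO replicate 4 has 345 above and 26 below, and the highest number above on any other array is 48.

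In the small intestine, a small set of probes differed between KO and WT. Of 26980 probes, 73 (0.271%) were called by limma, 53 lower and 20 higher in KO (27.4% higher), but without KO replicate 4 the calls were 56 lower and 53 higher (48.6% higher). The KO and WT arrays of every called probe did not overlap. With a mean below the dim limit raised to that limit, falls of at least 2-fold were found at 31 probes and rises at 10. Among called probes the log2 difference ranged from −7.49 to 4.53, with a median of −1.20 for the lower and 1.06 for the higher probes (−1.11 and 1.02 with dim means at the limit). An unadjusted p under 0.05 was reached by 3504 probes. Over all probes tested, the KO and WT arrays did not overlap at 2228 (8.26%), where chance gives 2.86%.

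The called probe with the largest rise, A_51_P169476, had a log2 intensity of 12.47 ± 1.11 (SD, n = 4) in KO and 7.94 ± 0.534 (SD, n = 4) in WT small intestine, a difference of 4.53 ± 0.49 (SE) or 23.0-fold (limma, adjusted p = 0.00627). The same probe rose in KO colon, from 7.27 ± 0.293 to 10.54 ± 0.631 (SD, n = 2 each), by 3.27 ± 0.693 (SE, limma, adjusted p = 0.0149). A_51_P145132 rose by 4.01 ± 0.451 (SE), from 7.94 ± 0.262 to 11.94 ± 1.11 (SD, n = 4 each; limma, adjusted p = 0.00643). Its difference in colon was 1.99 ± 0.637 (SE) and did not pass (limma, adjusted p = 0.0762), and the interaction did not separate the tissues for either probe (limma, adjusted p = 0.633 and 0.278). A_51_P279693 fell below the dim limit in all 4 KO arrays of small intestine, at 5.68 ± 0.0971 against 10.81 ± 1.27 (SD, n = 4 each), a loss of at least 16.7-fold (limma, adjusted p = 0.00383). The largest difference among called probes belonged to A_51_P162984, with 9.11 ± 3.08 in KO and 16.60 ± 0.901 in WT (SD, n = 4 each), or −7.49 ± 1.20 (SE, limma, adjusted p = 0.0357). Its KO arrays were split, with 13.73 in KO replicate 1 and 7.35 to 7.78 in the other 3. The difference was −9.03 without KO replicate 1, and −6.90 with the call lost (adjusted p = 0.0597) without KO replicate 4. In all, the probe lost its call under 10 of 16 alternatives, with adjusted p up to 0.118.

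**Figure D3:**
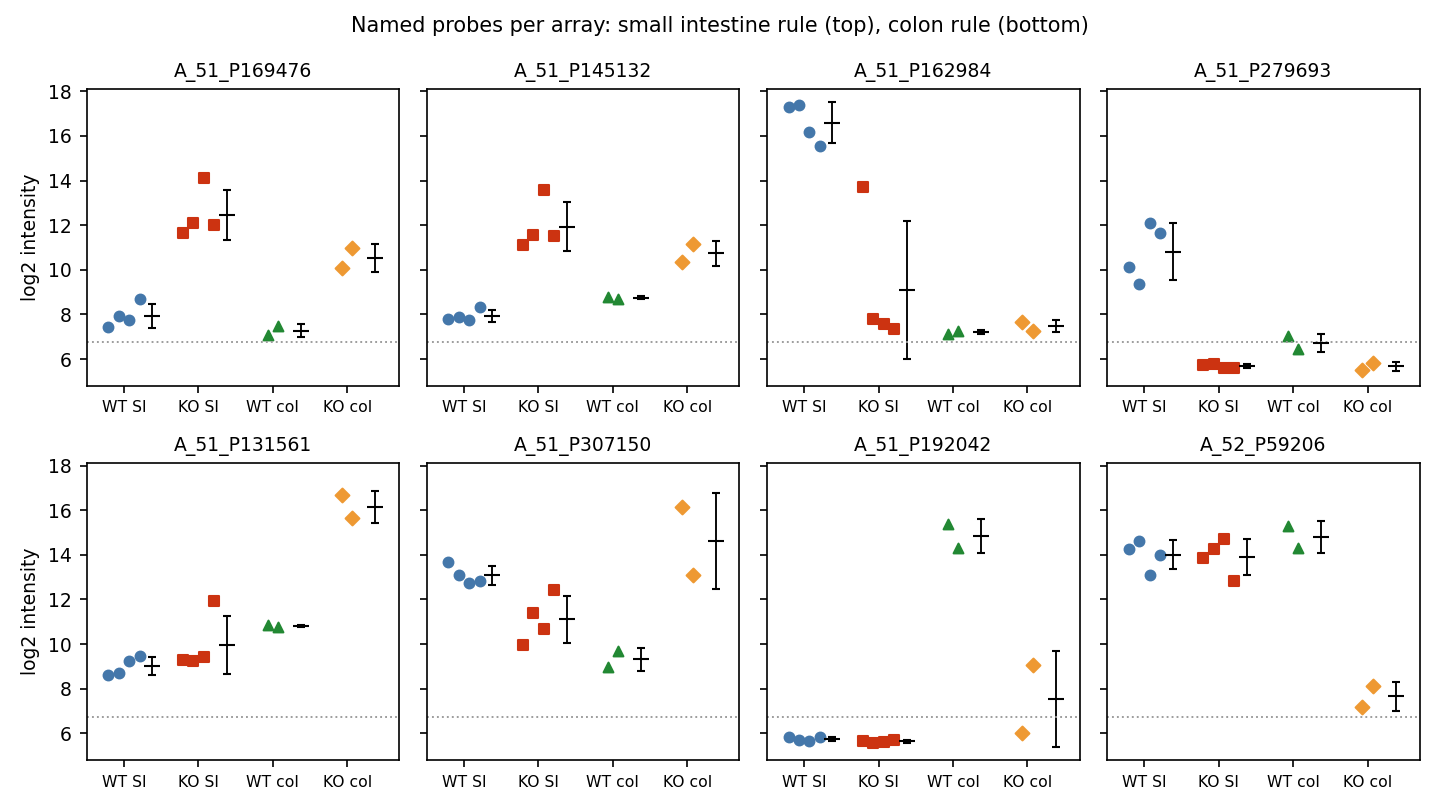
Log2 intensity of the 8 named probes on each of the 12 arrays (WT SI and KO SI, small intestine, 4 arrays each; WT col and KO col, colon, 2 each), with black marks and bars for the group mean and SD and a dotted line at the dim limit of 6.75. The top panels hold the called probes with the largest rises and falls in small intestine and the bottom panels those in colon, among them A_52_P59206, which is at 14.80 in WT colon and 7.65 in KO colon.

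The number of calls in small intestine depended on single arrays. Probes higher in KO numbered 4, 11 and 53 without KO replicates 2, 3 and 4, and 6, 11 and 8 without WT replicates 1, 2 and 3, and probes lower in KO numbered 30 without KO replicate 2 and 23 without WT replicate 1. With array weights, which gave KO replicate 4 a weight of 0.198, 181 probes were higher and 177 lower (50.6% higher), and with the small intestine arrays alone 8 were higher and 32 lower. With the replicate number as a block, 0 were higher and 3 lower. Under that block A_51_P169476, A_51_P145132 and A_51_P279693 also lost their calls (limma, adjusted p = 0.0534 each).

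The colon showed many more differences, in about equal numbers each way. Of the same 26980 probes, 2675 (9.91%) were called by limma, 1321 higher and 1354 lower in KO, with no overlap between the KO and WT arrays at any of them. With a mean below the dim limit raised to that limit, 124 probes fell and 48 rose by at least 8-fold, and 722 fell and 685 rose by at least 2-fold. At 320 of the lower probes the KO mean lay below the dim limit, and at 132 of the higher probes the WT mean did. The median log2 difference was −1.13 for the lower and 1.06 for the higher probes (−1.05 and 1.03 with dim means at the limit). With 2 arrays per genotype, no overlap alone is weak evidence: it held at 16608 of all probes (61.6%), where chance gives 33.3%.

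A_52_P59206, bright in both genotypes of small intestine, dropped from 14.80 ± 0.706 in WT colon to 7.65 ± 0.648 in KO colon (SD, n = 2 each), a log2 difference of −7.15 ± 0.622 (SE) or 142-fold (limma, adjusted p = 6.54e-05). A_51_P192042, below the dim limit on all small intestine arrays, fell from 14.86 ± 0.771 to 7.56 ± 2.15 (SD, n = 2 each), a log2 difference of −7.30 ± 0.709 (SE, limma, adjusted p = 0.00015). That SE also rests on the dim small intestine arrays, with SDs of 0.054 in KO and 0.101 in WT. With the colon arrays alone the adjusted p was 0.0398 (limma). Of its KO colon arrays, replicate 1 lay below the dim limit at 6.03 and replicate 2 above it at 9.08, and the difference was −5.78 without KO replicate 1. Without KO replicate 2 the remaining KO array lay below the dim limit, so no size is given. The largest rise among called probes was that of A_51_P131561, from 10.81 ± 0.0421 to 16.15 ± 0.728 (SD, n = 2 each), by 5.34 ± 0.761 (SE) or 40.5-fold (limma, adjusted p = 0.00172). A_51_P307150 rose from 9.32 ± 0.519 to 14.61 ± 2.15 (SD, n = 2 each), by 5.29 ± 0.907 (SE, limma, adjusted p = 0.00503). Its KO arrays lay at 16.13 and 13.09, so that the rise was 3.77 without KO replicate 1 and 6.81 without KO replicate 2. It lost its call without WT colon replicate 1 (adjusted p = 0.0563) and with the colon arrays alone (adjusted p = 0.0616), the latter being the largest adjusted p over 13 alternatives. Counts of calls in colon moved with each array left out, the lone array of that arm being assumed to vary like the other groups: 308 higher and 453 lower without KO replicate 1, 1528 and 1618 without KO replicate 2, 300 and 435 without WT replicate 1, and 549 and 666 without WT replicate 2. They were 517 and 606 with the colon arrays alone, and 2053 probes were lower in a fit without KO small intestine replicate 4.

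The KO effect differed between the tissues at 707 probes by the interaction test of limma, being higher in colon at 307 and lower at 400. Of these probes, 690 were called in colon and 11 in small intestine. At 25 of the 307 and 256 of the 400, both genotypes lay below the dim limit in small intestine, where no KO effect could be measured, and at 1 of the 307 both did in colon. Where at least 1 genotype of each tissue reached the dim limit, the balance was the other way, with 281 higher and 144 lower in colon. A_52_P59206 had an interaction of −7.06 ± 0.762 (SE, limma, adjusted p = 0.000552), with a KO level of 13.91 ± 0.796 (SD, n = 4) in small intestine and a difference from WT there of −0.09 ± 0.44 (SE, limma, adjusted p = 0.953). A_51_P307150 rose in KO colon, and its small intestine means were 11.12 ± 1.06 in KO and 13.08 ± 0.418 in WT (SD, n = 4 each), a difference of −1.96 that did not pass (limma, adjusted p = 0.24). Its interaction was 7.25 ± 1.11 (SE, limma, adjusted p = 0.00557), and 5.73 and 8.77 without KO colon replicates 1 and 2. For A_51_P131561 the interaction was 4.37 ± 0.932 (SE, limma, adjusted p = 0.034), and 5.02 without KO small intestine replicate 4 (adjusted p = 0.00023), but it lost its call on leaving out any 1 of 10 of the 12 arrays, all but that array and KO colon replicate 2 (adjusted p up to 0.193). No size is given for A_51_P192042, below the dim limit in both genotypes of small intestine, or for A_51_P279693, below it in both genotypes of colon. Probes with a higher effect in colon numbered 169 and 155 without KO small intestine replicates 1 and 2, 185, 198 and 166 without WT small intestine replicates 1, 2 and 3, 89 and 605 without KO colon replicates 1 and 2, and 51 without WT colon replicate 1, while the number with a lower effect moved by more than 1.5 times only without WT colon replicate 1 (244) among the arrays left out. With array weights the numbers were 499 and 609, and with a dim filter at the 60th percentile 239 probes had a higher and 225 a lower effect in colon.

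Calls in both tissues mostly shared a direction. Of the 53 probes lower in KO small intestine, 33 were also called lower in KO colon, where independent lists would share 2.7 (Fisher's exact test, two-sided, p = 6.91e-30, adjusted p = 2.76e-29). Of the 20 higher probes, 8 were also called higher in colon, against 0.98 for independent lists (Fisher's exact test, two-sided, p = 2.4e-06, adjusted p = 4.8e-06). No probe lower in KO small intestine was called higher in KO colon (Fisher's exact test, two-sided, p = 0.114, adjusted p = 0.152), and 2 probes higher in KO small intestine were called lower in colon (exact p = 0.266, adjusted p = 0.266). Called or not in colon, 62 of the 73 small intestine probes had the same sign there, as did 2075 of the 2675 colon probes (77.6%) in small intestine. Over all probes the KO effects of both tissues correlated at 0.303, and 1 other split of the 8 small intestine arrays gave a correlation of the same size, 0.303. No array entered the group means of both KO comparisons, but both used the same estimate of the spread per probe, from all arrays together. A probe with a small estimated spread is thus more readily called in both tissues. This can raise the overlap above that of independent lists, and Fisher's exact test does not allow for it. The labels also do not say whether the colon and small intestine samples came from the same mice. If they did, differences between animals would enter both comparisons, which the test does not allow for either.

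The overlap depended on single arrays. Probes lower in KO in both tissues numbered 18 without WT small intestine replicate 1, 20 without KO colon replicate 1 and 21 without WT colon replicate 2. Probes higher in both numbered 3, 1 and 27 without KO small intestine replicates 1, 2 and 4, 2 without WT small intestine replicate 1 and 4 without each of the other WT small intestine replicates, 23 without KO colon replicate 2, and 2 and 3 without WT colon replicates 1 and 2. With array weights, 76 probes were lower and 78 higher in both tissues, and with the replicate number as a block 1 was lower and 0 were higher.

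**Figure D4:**
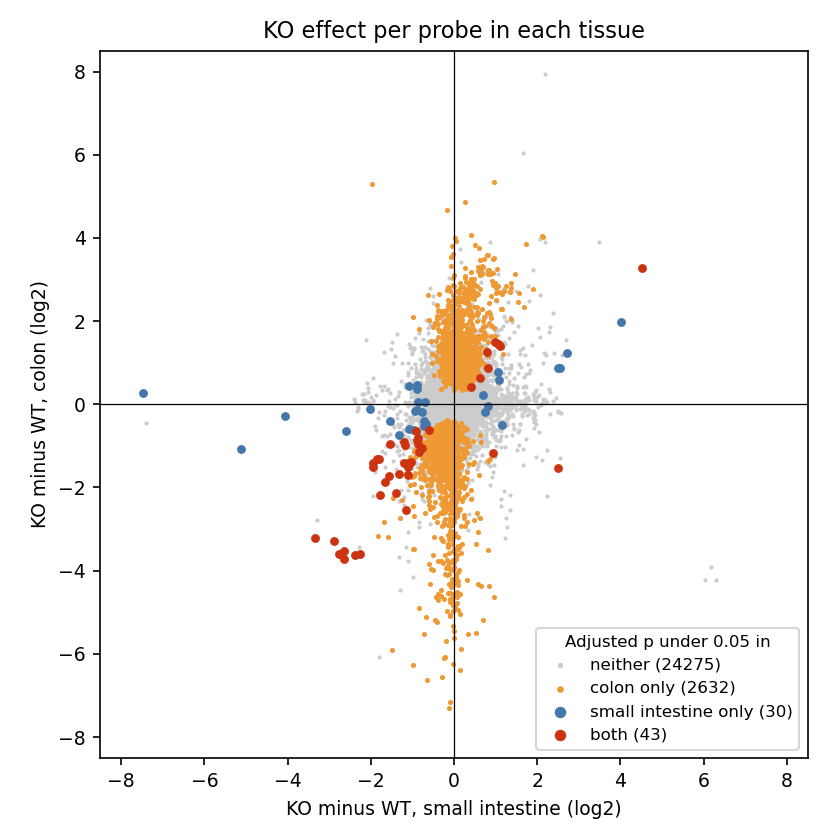
Each point is 1 of the 26980 probes, with the log2 difference of KO minus WT in small intestine (horizontal) and in colon (vertical), coloured by the tissue in which limma called it. Of the probes called in both tissues, 33 lie at the lower left, 8 at the upper right and 2 at the lower right.

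Colon and small intestine of WT mice differed at 8679 of 26980 probes (32.2%), 4838 higher in colon and 3841 higher in small intestine (limma). A_51_P192042 was among the probes higher in WT colon, at 14.86 ± 0.771 (SD, n = 2) against 5.76 ± 0.101 (SD, n = 4) in WT small intestine (limma, adjusted p = 1.16e-06), and A_51_P162984 among those higher in WT small intestine, by −9.39 ± 1.47 (colon minus small intestine, SE, limma, adjusted p = 0.000615). Without WT colon replicate 1 there were 2905 and 1980 such probes, and without WT colon replicate 2 there were 3172 and 2310.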

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

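The tests of added RNA and of the tissue label, the split test of probes called the same way in both tissues, and the comparisons of the genotype label with left-out WT arrays and matched probes, were chosen after the deviation of the array concerned had been seen. The other splits of the arrays, the loess test and the test of the genotype label by the midpoint were set before their results were seen.

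The number of calls in small intestine lay beyond what other groupings of the same arrays gave. Of the 35 splits of the 8 arrays into 4 and 4, 1 gave as many calls, the real one, with 73 calls against 15 for the highest other split. Ranking first is the strongest result that 35 splits can give. The splits also treat the arrays as separate animals, which the labels do not state. Without KO replicate 4 the real split was again 1 of 35, with 109 calls against 25. Taking from every split the 73 probes with the smallest p, 41 were called in the same direction in colon for the real split, 1 of 35, and 19 for the highest other. The number of 73 was itself set by the real split. The colon calls were those of the main fit for every split, and their spread per probe was estimated with the real grouping. That favours the real split, so this test does not remove the effect of the shared spread on the overlap. Chance cannot be excluded for the correlation of the KO effects between tissues, where 2 of 35 splits were as large in size. They were the real one with 0.303 and another with 0.303 or −0.303, the sign depending on which set of 4 is taken as KO.

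KO small intestine replicate 4 stood apart in its mean correlation with the other small intestine arrays, with a gap of 0.953 of the range of the 4 KO arrays, above the 95% critical value of Dixon's test. Its levels at the 345 probes above the other arrays by more than 3 log2 units had a median of 12.60, against 7.09 in the others, and 113 of these probes were dim in the others. An intensity curve left in these values was too small to account for the 345 probes. A loess curve of this array against the others shifted probes by a median of 0.211 and at most 0.30 log2 units. After its removal, 100% of the 345 stayed above by more than 3. With the same distribution on every array such a curve can hardly be large, so this test could hardly come out otherwise. A colon sample under this label is argued against by its mean correlation with colon minus that with small intestine arrays, −0.066. Of the 109 probes called without this array, 69.7% lay on the KO side in it. That is under the 80% set beforehand, so the rule set beforehand did not decide against a WT sample. The share was 87.3% to 91.2% for the other KO arrays when left out and 31.9% at most for left-out WT arrays. It was 89.3% of the lower and 49.1% of the higher probes, against 33.3% and 27.3% at most for WT arrays and 18.2% and 9.94% of matched other probes. Beyond all WT arrays on the KO side lay 79.8%, against 96.4% to 100% for the other KO arrays. Left-out WT arrays, compared with 3 arrays in place of 4, had 31.0% to 61.2%. A WT sample is thus argued against only by comparisons chosen afterwards. Of the probes off by more than 3 log2 units, 93.0% lay above, which RNA from another tissue or cell type in this sample would give. The share rests on the same probes that set the array apart. It is not specific to added RNA: WT small intestine replicate 4 had 48 above and 9 below, though WT replicate 1 had 14 and 24. Added RNA stays open with a real difference of that animal, which was not tested, and the source was not examined by gene.

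WT small intestine replicate 4 had the lowest mean correlation of the WT arrays, with a gap of 0.922 of their range, although the correlations of that group with the other small intestine arrays span only 0.972 to 0.975. At A_51_P162984, KO small intestine replicate 1 lay apart from the other KO arrays, with a gap of 0.933 of the range. At A_51_P131561, KO small intestine replicate 4 did, with a gap of 0.928. These were found in 18 tests, and for normally distributed values chance finds such an array in about 1 of 20. Over all 26980 probes, some array lay apart at 9.19% of probes in the KO group and 5.76% in the WT group. KO replicate 4 was the array apart at 6.97% of probes, and the other KO arrays at 0.486% to 1.16%.

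The KO effect differed between the tissues by the interaction test of limma, with a higher effect in colon at 307 probes and a lower one at 400. Among named probes the effect in colon minus that in small intestine was 4.37 for A_51_P131561 (5.02 without KO small intestine replicate 4, with the call lost on leaving out any 1 of 10 of the 12 arrays), 7.25 for A_51_P307150 (5.73 and 8.77 without KO colon replicates 1 and 2) and −7.06 for A_52_P59206. At 256 of the 400 probes and 25 of the 307, both genotypes of small intestine lay below the dim limit, so that a KO effect there could not be measured. Where at least 1 genotype of each tissue reached that limit, the effect was higher in colon at 281 probes and lower at 144. The larger number of lower effects thus rests on probes dim in small intestine.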

How the results depend on the processing

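The fit without the outlying array was chosen after seeing the data, and the other alternatives before. Quantile normalization, scaling to the 75th percentile and a variance model without trend kept every count within 1.5 times and every named probe's call, but the deposited values were already quantile normalized, so the scaling alternatives could move little. Chosen for no overlap, the 8 named probes could hardly change sign, and none did. A_51_P131561, A_51_P192042 and A_52_P59206 kept their calls in all 13 alternatives, A_51_P307150 in 11 of 13, and A_51_P162984 in 6 of 16. A_51_P169476, A_51_P145132 and A_51_P279693 lost the call only with the replicate block (adjusted p = 0.0534, their largest over 16).

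Without a dim filter, 10 probes were higher in KO small intestine and 3 higher in both tissues. With the filter at the 60th percentile, 239 probes had a higher and 225 a lower effect in colon than in small intestine. Array weights gave 181 higher and 177 lower in KO small intestine, all 73 calls kept, 499 and 609 for the interaction, and 76 lower and 78 higher in both tissues. The share of higher calls in small intestine was 27.4%, 50.6% with array weights and 48.6% without KO replicate 4. With the arrays of the compared tissue alone there were 8 higher and 32 lower in small intestine, and 517 and 606 in colon, where fewer arrays estimate the spread and 878 of the 1123 calls were among the 2675. The fit without the outlying array gave 1926 higher and 2053 lower in KO colon, 5616 higher in WT colon and 4713 in WT small intestine, beyond the ranges below, since that array is in none of those groups, and 27 higher in both tissues. Unless named, the cause was not tested.

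Leaving out each array of the groups compared in turn gave 4 to 53 higher and 23 to 57 lower in KO small intestine, 300 to 1528 and 435 to 1618 in KO colon, 51 to 605 higher and 244 to 588 lower effects in colon, 2905 to 4529 higher in WT colon and 1980 to 3580 in WT small intestine, and 18 to 38 lower and 1 to 27 higher in both tissues. Where a colon arm kept 1 array, that array was assumed to vary like the other groups. The range for the higher probes of small intestine ends at 53 without KO replicate 4, which kept 62 of the 73 calls.

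Deviations of same-numbered KO and WT arrays correlated at −0.06, −0.05, −0.14 and 0.01 in small intestine and −0.06 and −0.06 in colon. No array matched its own number best. These values gave no sign of pairing by replicate number, but the check is weak. In colon the deviations within each group mirror each other, so both values are equal by construction. Whether the replicate numbers paired the arrays was therefore not settled, and the block fit cannot be set aside on this ground. With the replicate number as a block, limma called 0 probes higher and 3 lower in KO small intestine (1007 and 1681 at an unadjusted p under 0.05), 561 and 631 in colon, 115 and 229 for the interaction, and 1 lower and 0 higher in both tissues. The block left 4 residual degrees of freedom in place of 8, and gave no tissue comparison. Planned but not run were log2 of the value plus 50 (the table is on a log scale), the mean of all probes of a gene and all tests of gene lists (no gene names). Weak signal limits the folds: 10 of the 73 called probes in small intestine and 452 of the 2675 in colon lay below the dim limit in the dimmer group.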

Other observations

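The selection of probes seen in WT colon and in no small intestine group was made after the colon calls had been seen, and the test of the shared arrays was set before its result was seen.

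The colon losses fell mostly on probes that mark WT colon against WT small intestine. Of the 1354 probes lower in KO colon, 1040 were higher in WT colon than in WT small intestine, 69 were lower there and 245 did not differ by the test, where independent lists would share 243 with the first kind. Of the 1321 probes higher in KO colon, 378 were higher in WT small intestine, against 188 for independent lists, and 85 were higher in WT colon. Of the 53 probes lower in KO small intestine, 15 were higher in WT colon and 19 in WT small intestine, where independent lists would share 9.5 and 7.5. Of the 20 probes higher in KO small intestine, 9 were higher in WT colon and 1 in WT small intestine, against 3.6 and 2.8. The WT small intestine arrays enter both of these comparisons.

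Both comparisons use the WT colon arrays, which by itself gives a negative relation. Across probes the covariance of the KO effect in colon with the tissue difference was −0.291 (r = −0.393), against a mean of −0.0608 (r = −0.158) in 20 simulations with an unchanged KO colon, a difference of −0.231. With a different WT colon array in each comparison the covariance was −0.236 and −0.293, a loss of 19.1% at most. This argues against variation private to single WT colon arrays as the whole source. A deviation common to both WT colon arrays would stay in both comparisons, and the simulations drew the arrays independently, so neither check addresses it. No biological explanation was tested, and a colon segment or mix of cells that differed between the KO and WT samples stays open.

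The extreme of this pattern is a set of probes bright in WT colon, by more than 2 log2 units above the dim limit, and dim in both small intestine groups. Of 166 such probes, 67 (40.4%) were dim in KO colon too, with a median log2 intensity of 6.18 there. The mirrored selection, bright in KO colon and dim in small intestine, held 68 probes, of which 5 (7.35%) were dim in WT colon. At these 5 the KO colon replicates differed by a median of 3.4 log2 units (replicate 1 minus 2), against 0.62 between the WT colon replicates at the 67. A loss in KO colon and a colon segment or other tissue present in both WT colon samples alone cannot be told apart for these 67 probes, since genotype and sample go together with 2 arrays each and the probes were not matched to genes.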
